A study of Zea mays with 109 samples.

How the data were processed

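Tissues of the maize inbred line B73 were grown under 12 h of light and 12 h of dark at 25 °C, per the labels' protocols. For each tissue, RNA from 3 replicates of 5 to 10 plants was mixed in equal amounts, so 1 library stood for 1 tissue. The 109 samples held 26 total RNA libraries, 26 small RNA libraries, 26 circular RNA (circRNA) libraries, 20 libraries of RNA bound by ribosomes and 11 cDNA pools behind a list of protein pairs. Tissues were grouped into organ classes by their names in the labels. The total RNA, small RNA and circRNA sets each had 11 leaf, 6 inflorescence, 3 SAM, 2 root, 2 stem, 1 embryo and 1 endosperm library. The ribosome-bound set had 8 leaf, 4 inflorescence, 2 SAM, 2 root, 2 stem, 1 embryo and 1 endosperm library. Because no tissue had replicate libraries, the tissues of a class were the units of every test, and p-values measure the spread between tissues of a class, which differ in organ age and position. The leaf class of the total RNA, small RNA and circRNA sets held 4 pairs of libraries from the same leaf position, with the letters L and N described below. Comparisons of leaf with other organs counted the members of a pair as separate units. Pair members were correlated, as given below, so the p-values of these comparisons may be too small. The labels gave no sequencing batch or date.

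The submitters' processing notes name the maize build B73 RefGen_v4 and the tools HISAT, StringTie, Bowtie 1.1.2, RSEM, SAMtools 1.9 and cutadapt 1.9.1 for the whole series, without the role of each tool. Total RNA values were deposited by the authors as TPM, and the listed entries summed to 159407 to 395863 TPM per library, so the entries that made up the rest of the TPM scale were not used here. Ribosome-bound values were deposited by the authors as TPM, and each library summed to 1000000 TPM. Small RNA values were named TPM in the deposited table but behaved as log2(TPM + 1), since the back-transformed columns summed to 995605 to 999027, so the deposited log2 values were tested without another log step. The circRNA values were deposited as CPM by name but were treated as a signal, because most columns summed to more than counts per 1000000 reads can. In every circRNA library 100% of the signal values were whole multiples of a fixed step of that library within a tolerance of 0.001, so whole reads were recovered, 17289 to 107480 per library. With 1 factor for all libraries, the signal equalled reads divided by a library number that lay at most 0.00552 from a whole number. In the 1cm Ear a summed signal of 2.65e+06 was 2646 reads per 1000000 of this number. The library number was 15619436 to 36058364, and its meaning is not given in the sources used here. The list of protein pairs was deposited by the authors without a score, a pool or a count per pair. TPM and log2 values keep no read depth, so the depth behind them is unknown and no counting interval is given. A single line of the total RNA data held 2 records and was split. These findings on the small RNA and circRNA scales departed from the units that the design had assumed.

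The files do not pair identifiers with gene names. Of 50738 identifiers of genes, transcripts and partners, 0 matched the 49888 genes of the reference table given for the assembly Zm-B73-REFERENCE-NAM-5.0. Therefore none of the 21 gene lists fixed beforehand, the miRNA families and the small RNA length classes could be measured, and entries are reported by identifier only. The total RNA table listed 37069 gene models, 7581 entries whose names start with ZmLnc, 2512 transcript entries and 940 entries whose names start with ZmmRNA, and the sources used here do not say what these prefixes stand for. The ribosome-bound table listed 39324 gene models, the small RNA data held 144158 features and the circRNA data 61936 features.

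Tests used limma 3.58.1 with a mean-variance trend in R 4.3.3, on log2(TPM + 1), with 1 fit over all organ classes of an assay and the organ class as the factor. Entries with at least 1 TPM in at least 2 libraries were tested. Ears and tassels were separate classes in the comparison between them. An entry was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. A fold change on the log2(value + 1) scale understates the change of low entries. The ratio of ribosome-bound to total RNA was tested as the difference of both log2 values of a tissue. For circRNAs the pseudocount was the smallest positive signal, 27.7, and a circRNA had to be above 0 in at least 5 libraries, or in at least 2 of the 8 leaf libraries compared for the letters L and N. As an alternative, edgeR 4.0.16 with quasi-likelihood tests was run on the recovered reads. Means per library were compared by two-sided exact permutation tests over all 12376 splits of the 17 inflorescence and leaf libraries.

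Leaves carrying the letters L and N, which the labels do not explain, were compared in 4 pairs of a leaf position, with the position as a block. The labels name the same leaf position in both members of a pair. Deviations from the letter means correlated between the members of a pair at 0.577 for the base of the stage 2 leaf, 0.853 for the first leaf, 0.544 for the tip of the stage 2 leaf and 0.756 for the topmost leaf, so the positions paired the libraries.

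Named entries followed 1 rule, the 2 entries with the largest fold change in each direction among the called entries whose libraries did not overlap between both classes. For circRNAs the 5 with the highest summed signal were added, and for protein pairs the 5 proteins with most partners. Embryo and endosperm, with 1 library each, were described without a test by the entries of at least 10 TPM that were 4-fold above every other library on the log2(TPM + 1) scale. Protein pairs were compared for Pearson's r of log2(TPM + 1) over the 26 total RNA libraries against 1000 shuffles of partners, which kept each protein's number of partners, and against 200 shuffles in the alternatives. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for these steps and the figures. The organ classes, tests, thresholds, naming rule and first set of alternatives were chosen before the data were examined. The comparison of SAM with inflorescence, the grouping of entries by name prefix, the pair directions and the alternatives named as added later were chosen after seeing the data.

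Each fit was tested on simulated data with 200 changed entries at log2 folds of 1, 2 and 3. The share recovered was 36.8%, 95.5% and 98.5% for total RNA of inflorescence against leaf over 24997 entries, 44.1%, 95.5% and 98.5% for SAM against leaf, 19.1%, 77.3% and 93.9% for root against leaf and 14.7%, 77.3% and 97.0% for stem against leaf. For ear against tassel it was 8.82%, 62.1% and 83.3%, for leaf L against N 26.5%, 83.3% and 98.5% over 16238 entries, and for SAM against inflorescence 23.5%, 81.8% and 90.9%. Ribosome-bound RNA gave 13.2%, 60.6% and 97.0% over 25807 entries, and its ratio to total RNA 17.6%, 68.2% and 90.9% over 19620 entries. Small RNAs of inflorescence against leaf gave 52.9%, 100% and 100% over 98273 features, and of L against N 38.2%, 100% and 100% over 86843 features. For circRNAs of inflorescence against leaf, limma recovered 16.2%, 72.7% and 95.5% and edgeR 1.47%, 22.7% and 50.0% over 8989 features. For circRNAs of L against N, limma recovered 0%, 0% and 1.52% and edgeR 0%, 6.06% and 18.2% over 6655 features. The limma simulations used the spread fitted to these data, while the edgeR simulations used an assumed spread and 1 mean per circRNA. The edgeR shares therefore do not give its power in these data. False calls numbered 0 to 6 per simulated fit. A call needed an absolute log2 fold change of at least 1, so noise alone kept many entries changed by 1 below it. The share at a fold of 1 is therefore limited by the threshold as well as by power. The 200 changed entries were also far fewer than the 11820 called in total RNA of inflorescence against leaf. The shares and false calls may thus not carry over to the real data. In simulated pairs of independent profiles over 8000 genes the shuffles gave a permutation p of 0.3, and pairs planted at r = 0.7 gave a median r of 0.708 with a permutation p of 0.005, the smallest that 200 shuffles can give.

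Alternatives covered pseudocounts of 0.1 and 5, no filter on low values, quantile normalization, fits of the compared classes alone, fits without the block, median-ratio rescaling and a filter of 10 for small RNAs, a pseudocount 10 times larger and a stricter detection filter for circRNAs, Spearman's rho for pairs, and leaving out each library of a class of 2 to 5. Quantile normalization gives every library of a table the same distribution and so removes a shift shared by most entries. A near-even split of calls after it is therefore partly set by the method. Because no gene list could be measured, set tests on those lists and the ratio of their ribosome-bound to total RNA were not run. Pairs listed in more than 1 pool could not be singled out.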

Results

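The data covered 26 tissues or stages of maize, from primary roots and leaves to the developing ear and tassel, the female and the male inflorescence, and the embryo and endosperm of the kernel. Total RNA, small RNA and circRNA were each measured in 26 libraries and ribosome-bound RNA in 20, and 11 cDNA pools stood behind a list of protein pairs. SAM is the usual abbreviation of the shoot apical meristem, the stem cell region at the shoot tip. At least 1 TPM was listed for 17103 ± 1446 total RNA entries (SD, n = 6) in inflorescence libraries and for 13296 ± 1197 (SD, n = 11) in leaf libraries, a difference with an exact permutation p of 8.08e-05 (0.000404 after Benjamini-Hochberg adjustment over 5 library measures). The 10 most abundant entries of a library held 15.3% ± 5.12 (SD, n = 6) of its listed TPM in inflorescence and 39.2% ± 9.32 (SD, n = 11) in leaf (exact permutation p = 0.000162, adjusted 0.000404). In leaf, 1 gene model, Zm00001d000417, held 27.3% ± 8.62 (SD, n = 11) of the listed TPM, from 9.57% in the husk leaf to 37.7%, against 0.0738% ± 0.0333 (SD, n = 6) in inflorescence. The sum of listed TPM was 259350 ± 78192 (SD, n = 6) in inflorescence and 241139 ± 37054 (SD, n = 11) in leaf (exact permutation p = 0.534). It was 313958 ± 49182 (SD, n = 3) in SAM, 277777 ± 15036 (SD, n = 2) in root and 193099 ± 28588 (SD, n = 2) in stem, without a test. A higher listed sum raises most entries, so median shifts and counts against leaf are not comparable between these organs.

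Leaves stood apart from all other organs in total RNA, along a first principal component with 56.3% of the variance. The second component, with 10.4%, set both primary roots apart from the other tissues. The nearest library by Spearman's rho across entries, which are not independent replicates, lay in the same organ class for 23 of 24 total RNA libraries with a class partner, 18 of 18 ribosome-bound, 23 of 24 small RNA and 24 of 24 circRNA libraries. The number of libraries with identical values was 0 in each assay.

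**Figure D1:**
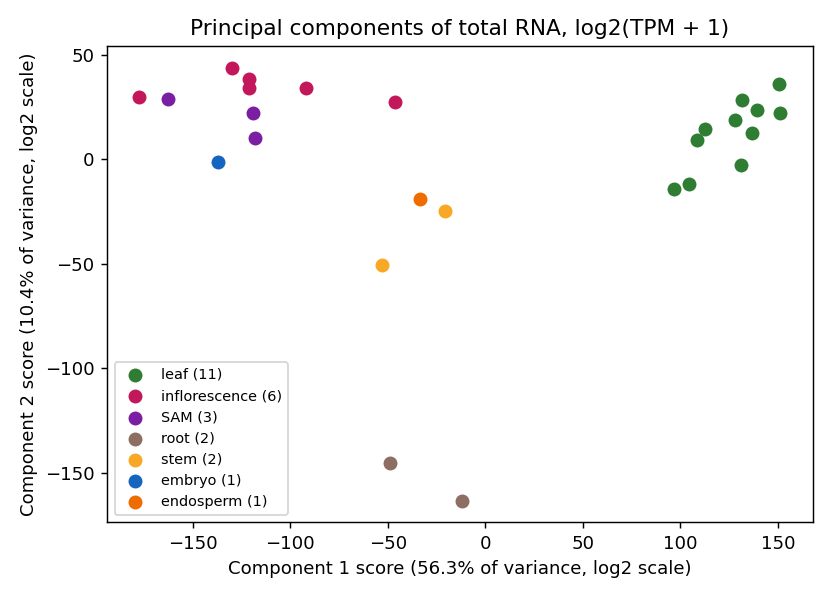
Scores of the 26 total RNA libraries on the first component (horizontal axis, 56.3% of variance) and the second component (vertical axis, 10.4% of variance) of log2(TPM + 1), with 1 point per library and colours for organ classes. The 11 leaf libraries lie to the right of all others, and both root libraries lie lowest.

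Inflorescence was compared with leaf to find the transcripts that differ between reproductive and photosynthetic organs. The gene model Zm00001d030698 was at 426 ± 426 TPM (SD, n = 6) in inflorescence, with 1267 TPM in the 2mm Tassel and 78.9 to 415 TPM in the others, and 0.0936 ± 0.196 TPM (SD, n = 11) in leaf, a log2 fold change of 8.13 (SE 0.399, adjusted p = 2.75e-13). Zm00001d021433 was at 310.1 ± 117 TPM (SD, n = 6) against 0.408 ± 0.287 TPM (SD, n = 11), a log2 fold change of 7.72 (SE 0.213, adjusted p = 9.37e-17). In leaf, ZmLnc006076 reached 5234 ± 1883 TPM (SD, n = 11) against 4.24 ± 3.16 TPM (SD, n = 6) in inflorescence, a log2 fold change of -10.15 (SE 0.419). Zm00001d023516 was at 2082 ± 2209 TPM (SD, n = 11) in leaf and 0.107 ± 0.152 TPM (SD, n = 6) in inflorescence, a log2 fold change of -10.02 (SE 0.631). Of 24997 entries tested with limma, 9199 were higher and 2621 lower in inflorescence. The median of all entries was shifted by 0.65 towards inflorescence, and relative to that shift, after quantile normalization, 4516 entries were higher and 4399 lower. Without Zm00001d000417 and with the other entries rescaled, an alternative chosen after seeing the data, 7106 were higher and 3439 lower. This rescaling held each library's listed sum fixed, although that sum is only part of the TPM scale. It may therefore overstate the effect of this entry. Without the husk leaf and the 1cm Tassel, the libraries with the lowest listed sums of their classes, 12922 entries were called.

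Entries with the ZmLnc prefix, a grouping chosen after seeing the data, were called higher in inflorescence in 726 of 3452 cases, against 7983 of 20342 gene models. The ZmLnc entries had a median log2 difference of 0.27 and the gene models of 0.72. ZmLnc entries also had lower levels, with a median highest value of 5.38 TPM against 10.8 TPM. Since the log2(TPM + 1) scale understates changes of low entries, the differences in calls, median and rank are not separated from level. By limma's camera test with a preset correlation, the ZmLnc entries ranked below the others with an adjusted p of 0.106, and against leaf in SAM with an adjusted p of 0.00982. No prefix class was called with an estimated correlation (adjusted p = 0.841 for inflorescence and adjusted p = 0.826 for SAM). Between ear and tassel the 43 entries with the GRMZM5G prefix ranked towards ear with the preset correlation (adjusted p = 4.05e-07) and not with the estimated one (adjusted p = 0.832). ZmLnc entries held 19.9% ± 5.57 (SD, n = 6) of the listed TPM in inflorescence and 15.1% ± 2.19 (SD, n = 11) in leaf (exact permutation p = 0.0143, adjusted 0.0179). The single entry ZmLnc005325 carried this difference, with 6.95% ± 4.23 (SD, n = 6) in inflorescence and 1.32% ± 0.502 (SD, n = 11) in leaf. Without it the other ZmLnc entries held 12.99% ± 1.92 (SD, n = 6) in inflorescence and 13.8% ± 1.88 (SD, n = 11) in leaf (exact permutation p = 0.425, chosen after seeing the data).

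The SAM libraries were set against leaf to find transcripts that differ between a meristem and leaves of several positions. Zm00001d030698, named above for inflorescence, was at 500.0 ± 408 TPM (SD, n = 3) in SAM, with 966 TPM in SAM(V4), 329 TPM in SAM(V1) and 205 TPM in SAM (V3), a log2 fold change of 8.54 (SE 0.512, adjusted p = 1.38e-11). Zm00001d050100 was at 421 ± 89.3 TPM (SD, n = 3) in SAM and 0.501 ± 0.909 TPM (SD, n = 11) in leaf, a log2 fold change of 8.26 (SE 0.430). Zm00001d023516 lay at 0.0867 ± 0.0115 TPM (SD, n = 3) in SAM, a log2 fold change of -10.04 (SE 0.810), and ZmLnc006076 at 7.46 ± 2.82 TPM (SD, n = 3), a log2 fold change of -9.19 (SE 0.538). In limma's test 10187 entries were higher and 2357 lower in SAM, with a median shift of 0.74. Part of this shift may lie in the higher mean listed sum of the SAM libraries. After quantile normalization 4601 were higher and 4318 lower.

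Primary root was compared with leaf. Zm00001d031909 was at 386 ± 196 TPM (SD, n = 2) in root and 0.0455 ± 0.0609 TPM (SD, n = 11) in leaf, a log2 fold change of 8.44 (SE 0.155, adjusted p = 9.72e-22). Its root values were 525 and 248 TPM, so the small SE reflects other classes with values near 0, and without either root library it did not pass the filter and was not tested. Zm00001d023994 was at 896 ± 63.4 TPM (SD, n = 2) in root and 3.50 ± 6.07 TPM (SD, n = 11) in leaf, a log2 fold change of 8.37 (SE 1.08). ZmLnc006076 was at 5.57 ± 0.0849 TPM (SD, n = 2) in root, a log2 fold change of -9.49 (SE 0.635). Zm00001d000417 was at 109.8 ± 9.30 TPM (SD, n = 2) in root and 67402 ± 24880 TPM (SD, n = 11) in leaf, a log2 fold change of -9.11 (SE 0.475). In limma's test 8531 entries were higher and 1568 lower in root, with a median shift of 0.65, and after quantile normalization 3235 were higher and 2688 lower. Without the Primary Root(6DAS) library the count of calls fell from 10099 to 6058.

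Stem and internode were compared with leaf as 1 class of 2 libraries. Zm00001d005472 was at 239.7 ± 52.7 TPM (SD, n = 2) in stem and 0.0855 ± 0.213 TPM (SD, n = 11) in leaf, a log2 fold change of 7.79 (SE 0.402, adjusted p = 8.11e-12). ZmmRNA011247 was at 223 ± 52.7 TPM (SD, n = 2) in stem and 0.246 ± 0.621 TPM (SD, n = 11) in leaf, a log2 fold change of 7.56 (SE 0.355). Zm00001d023516 was at 0.485 ± 0.332 TPM (SD, n = 2) in stem, a log2 fold change of -9.60 (SE 0.956). Zm00001d038163 was at 0.46 ± 0.283 TPM (SD, n = 2) in stem and 1018 ± 468 TPM (SD, n = 11) in leaf, a log2 fold change of -9.32 (SE 0.408). In limma's test 5454 entries were higher and 1980 lower in stem, with a median shift of 0.35, and after quantile normalization 3387 were higher and 3170 lower. Without the Internode(V6) library 3418 entries were called in place of 7434.

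**Figure D2:**
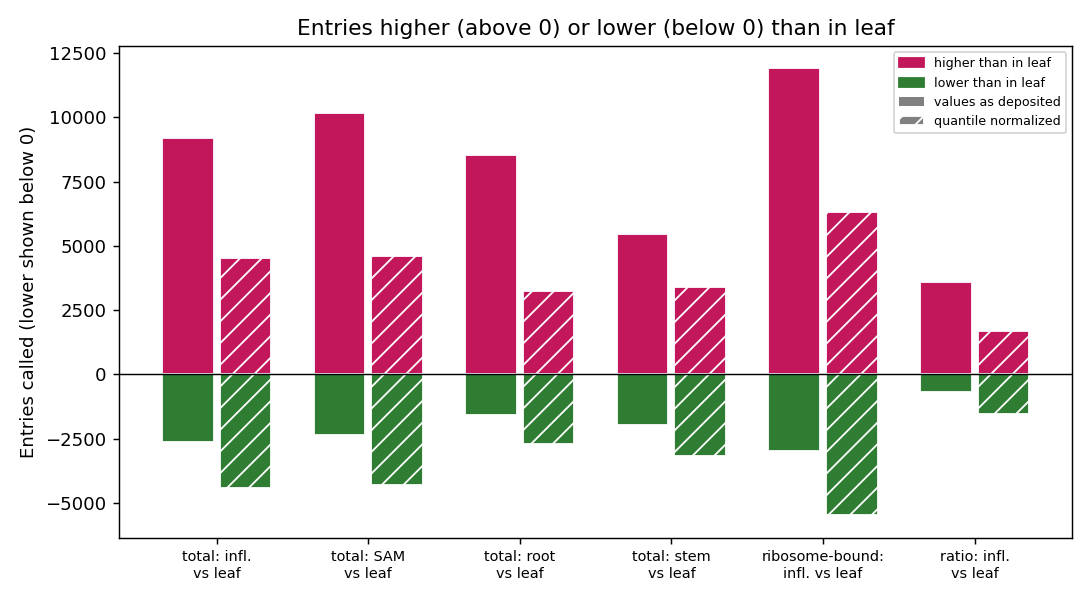
Number of entries called higher (above 0) or lower (below 0) than in leaf on the vertical axis, for 4 total RNA comparisons, ribosome-bound RNA and the ratio of both, with plain bars for the deposited values and hatched bars after quantile normalization. For total RNA of inflorescence the plain bars show 9199 higher and 2621 lower, and the hatched bars 4516 higher and 4399 lower.

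Ears, which bear the female flowers, were compared with tassels, which bear the male ones. Zm00001d033605 was at 35.1 ± 18.8 TPM (SD, n = 3) in ear and 2.42 ± 2.60 TPM (SD, n = 2) in tassel, a log2 fold change of 3.52 (SE 0.386, adjusted p = 9.55e-05). Zm00001d033673 was at 12.7 ± 2.93 TPM (SD, n = 3) in ear and 0.38 ± 0.184 TPM (SD, n = 2) in tassel, a log2 fold change of 3.30 (SE 0.231, adjusted p = 1.73e-07). In tassel, Zm00001d031657 was at 69.2 ± 20.5 TPM (SD, n = 2) against 6.19 ± 3.11 TPM (SD, n = 3) in ear, a log2 fold change of -3.36 (SE 0.580, adjusted p = 0.0122), and Zm00001d033044 at 17.3 ± 14.7 TPM (SD, n = 2) against 0.663 ± 0.266 TPM (SD, n = 3), a log2 fold change of -3.19 (SE 0.476, adjusted p = 0.00357). Both calls towards tassel ended at a pseudocount of 0.1, where the log2 fold changes were -3.58 (adjusted p = 0.0583) and -4.25 (adjusted p = 0.0770), so the folds did not shrink. In limma's test 15 entries were higher and 25 lower in ear, and after quantile normalization 32 were higher and 21 lower. The listed TPM sum was 395863 in the 2mm Tassel and 165539 in the 1cm Tassel, against 203910 to 265224 in the ears. This difference of scale between the tassels may set the direction of calls when 1 tassel is left out, which was not tested. Single libraries decided the count and its direction, with 29 higher and 818 lower in ear without the 1cm Tassel (847), 2336 higher and 180 lower without the 2mm Tassel (2516), 54 higher and 21 lower without the 2mm Ear (75) and 8 higher and 16 lower without the 5mm Ear (24).

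Leaves with the letter L were compared with leaves with the letter N at 4 positions. Zm00001d049543 was at 75.2 ± 26.8 TPM (SD, n = 4) in L and 0.698 ± 0.310 TPM (SD, n = 4) in N, a log2 fold change of 5.42 (SE 0.190, adjusted p = 0.000510). ZmmRNA011547 was at 61.2 ± 16.2 TPM (SD, n = 4) in L and 0.633 ± 0.0727 TPM (SD, n = 4) in N, a log2 fold change of 5.22 (SE 0.160). Zm00001d035310 was at 0.333 ± 0.135 TPM (SD, n = 4) in L and 36.1 ± 21.7 TPM (SD, n = 4) in N, a log2 fold change of -4.60 (SE 0.369), and Zm00001d041365 at 0.553 ± 0.249 TPM (SD, n = 4) in L and 31.0 ± 3.92 TPM (SD, n = 4) in N, a log2 fold change of -4.37 (SE 0.166). Of 16238 entries tested with limma, 566 were higher and 521 lower in L, while the median of all entries was shifted by -0.21. After quantile normalization 685 were higher and 293 lower. Without the block of leaf position the count of calls was 420 in place of 1087. At each position 563 to 566 of the 566 higher entries and 519 to 521 of the 521 lower ones had the sign of the call, which is partly set by the call itself. A 4-fold difference was seen in 3.48% of entries at the tip of the stage 2 leaf, 2.18% at its base, 1.69% in the first leaf and 1.24% in the topmost leaf.

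Ribosome-bound RNA held 1 pair of these letters, the first leaf, so the letters were not tested there. Over the 13804 entries tested in total RNA and listed in both tables, the difference between L and N in the first leaf correlated between total and ribosome-bound RNA with r = 0.744 and rho = 0.657 across genes, which are not independent replicates. Among the 939 called ones r was 0.923, a value raised by choosing entries from both extremes of total RNA. Relative to the median difference of ribosome-bound RNA, 485 of 503 entries higher in L and 420 of 436 lower in L lay on the side of their total RNA call, which the first leaf had helped to set.

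Ribosome-bound RNA of inflorescence was compared with that of leaf to find differences in the mRNAs that ribosomes carried. Zm00001d030698 was at 1542 ± 461 TPM (SD, n = 4) in inflorescence and 0.468 ± 0.611 TPM (SD, n = 8) in leaf, a log2 fold change of 10.08 (SE 0.419, adjusted p = 1.26e-11). Zm00001d002543 was at 4013 ± 1190 TPM (SD, n = 4) in inflorescence and a mean of 12.5 TPM in 8 leaf libraries, from 0 to 71.0 TPM, a log2 fold change of 9.56 (SE 0.854). Zm00001d023516 was at 0.823 ± 1.00 TPM (SD, n = 4) in inflorescence and 15598 ± 13269 TPM (SD, n = 8) in leaf, a log2 fold change of -11.49 (SE 1.77), with 3.14 TPM in the husk leaf. Zm00001d048611 was at 5.70 ± 6.12 TPM (SD, n = 4) in inflorescence and 6895 ± 3055 TPM (SD, n = 8) in leaf, a log2 fold change of -10.52 (SE 0.630). Of 25807 entries tested with limma, 11909 were higher and 2977 lower in inflorescence, with a median shift of 0.90, and after quantile normalization 6331 were higher and 5482 lower. The gene model Zm00001d019605, which the total RNA table used here does not list, held 27.8% to 62.5% of the ribosome-bound TPM in 6 of 8 leaf libraries. It held 1.77% at the base of the stage 2 leaf, 0.121% in the husk leaf and 1.31% in the embryo. Without it and with the other entries rescaled, an alternative chosen after seeing the data, 8975 entries were higher and 4435 lower, with a median shift of 0.41.

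**Figure D3:**
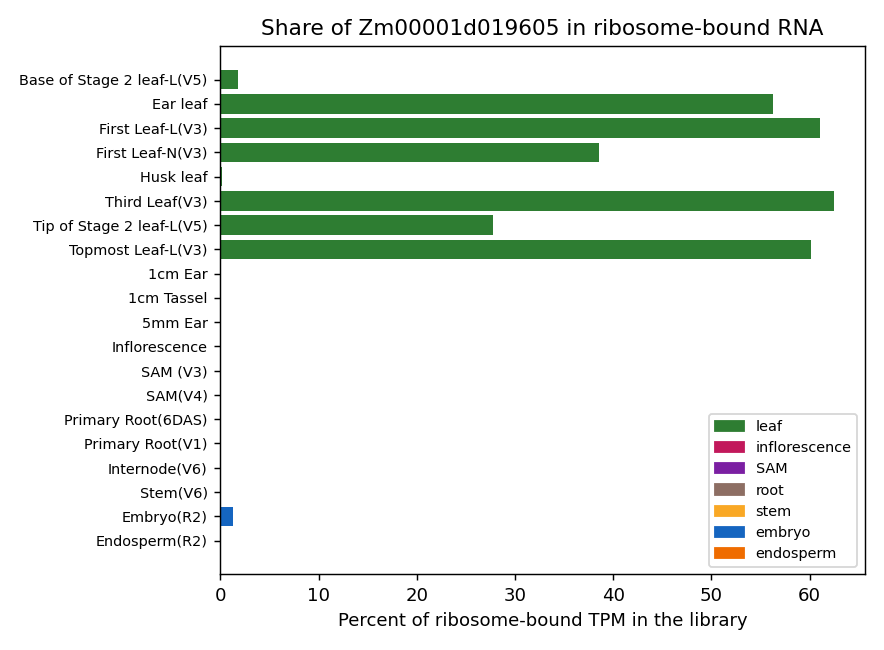
Share of the ribosome-bound TPM held by Zm00001d019605 (horizontal axis, percent) in each of the 20 libraries (1 bar each, coloured by organ class). The share is 27.8% to 62.5% in 6 leaf libraries, 1.77% at the base of the stage 2 leaf and 0.121% in the husk leaf.

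Across the 37127 genes listed in both tables, 18 of 20 ribosome-bound libraries were closest to the total RNA of their own tissue, with Spearman's rho from 0.866 to 0.915 across genes. The exceptions were the internode, closest to the stem, and SAM (V3), closest to SAM(V4). The ratio of ribosome-bound to total RNA was then compared between inflorescence and leaf. Zm00001d042527 had 95.4 ± 27.1 TPM ribosome-bound (SD, n = 4) and 1.48 ± 0.662 TPM in total RNA (SD, n = 4) in inflorescence, and was listed at 0 in the 8 leaf libraries of both tables. Zm00001d012165 had 137 ± 22.7 TPM ribosome-bound (SD, n = 4) and 2.48 ± 1.02 TPM in total RNA (SD, n = 4) in inflorescence, and was listed at 0 in total RNA of the 8 leaf tissues. Zm00001d009474 had 186 ± 166 TPM ribosome-bound (SD, n = 8) and 0.01 ± 0.0141 TPM in total RNA (SD, n = 8) in leaf, against 1.42 ± 0.695 TPM (SD, n = 4) and 0.805 ± 0.521 TPM (SD, n = 4) in inflorescence. Zm00001d045877 had 300.4 ± 297 TPM ribosome-bound (SD, n = 8) and 1.36 ± 0.330 TPM in total RNA (SD, n = 8) in leaf, and was listed at 0 in total RNA of 3 of the 4 inflorescence tissues. Because these 4 genes lay near 0 in total RNA, their ratios rest on the pseudocount and no fold is given. Of 19620 genes tested with limma, 3595 had a higher and 676 a lower ratio in inflorescence, with a median shift of 0.48. After quantile normalization 1677 were higher and 1544 lower, and without Zm00001d019605 and with the other entries rescaled 1848 were higher and 2267 lower. The count of 4271 fell to 2667 without the 1cm Tassel and rose to 7618 without the husk leaf and the base of the stage 2 leaf.

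Small RNA features were compared between inflorescence and leaf. ZmsRNA353320 was at 1.51 ± 0.475 TPM (SD, n = 6) in inflorescence and 307 ± 134 TPM (SD, n = 11) in leaf, a log2 fold change of -6.78 (SE 0.289, adjusted p = 9.84e-15). ZmsRNA362423 was at 1.80 ± 0.427 TPM (SD, n = 6) in inflorescence and 271 ± 141 TPM (SD, n = 11) in leaf, a log2 fold change of -6.43 (SE 0.288). In the other direction, ZmsRNA131345 was at 9.59 ± 4.42 TPM (SD, n = 6) in inflorescence and 0.384 ± 0.249 TPM (SD, n = 11) in leaf, a log2 fold change of 2.86 (SE 0.258). ZmsRNA302725 had nearly the same values, with a log2 fold change of 2.85 (SE 0.258), and whether both share reads is unknown because their sequences were not analysed here. Features of at least 1 TPM numbered 88592 ± 2678 (SD, n = 6) in inflorescence libraries and 78656 ± 7276 (SD, n = 11) in leaf libraries (exact permutation p = 0.00558, adjusted 0.00929). Of 98273 features tested with limma, 2946 were higher and 7332 lower in inflorescence, with a median shift of 0.45. The split depended on the scaling and on the pseudocount, with 89 higher and 9795 lower after median-ratio rescaling and 16518 higher and 8282 lower at a pseudocount of 0.1.

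Between leaves L and N, 2 small RNA features were called by limma, against 14949 of 86843 at an unadjusted p under 0.05. ZmsRNA043227 was at 1.66 ± 0.961 TPM (SD, n = 4) in L and 0.172 ± 0.159 TPM (SD, n = 4) in N, a log2 fold change of 1.11 (SE 0.0939, adjusted p = 5.26e-06), and ZmsRNA043237 had nearly the same values. Both calls ended without the block of leaf position, which left 0 calls (log2 fold change 1.11, adjusted p = 0.979), after median-ratio rescaling (1.05, adjusted p = 0.488) and without the pair from the tip of the stage 2 leaf (1.02, adjusted p = 0.737), so the direction was kept. The count was 9 without the base pair, 7 without the first leaf pair and 9 without the topmost pair.

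CircRNAs, closed RNA rings formed by back-splicing, were on average more numerous in inflorescence than in leaf, with the 2mm Ear as the exception. Inflorescence libraries listed 9551 ± 3035 circRNAs above 0 (SD, n = 6) and leaf libraries 4782 ± 836 (SD, n = 11), a ratio of 2.00 (two-sided exact permutation p = 0.000566, the same after adjustment over both circRNA totals). The summed signal was 2.19 times higher in inflorescence (exact permutation p = 0.000242, adjusted 0.000485). Thinned to the smallest library number, the ratio of detected circRNAs was 1.75 (exact permutation p = 0.000566). Thinned to a common 17289 circRNA reads per library, 4493 ± 491 circRNAs (SD, n = 6) were expected in inflorescence and 3943 ± 229 (SD, n = 11) in leaf, a ratio of 1.14 (exact permutation p = 0.00760). The 2mm Ear listed 4844 circRNAs, within the leaf range of 3646 to 5834, and at the common read number 3529, below every leaf library (3594 or more). Other organs also lay above the leaf mean, with 9597 ± 594 circRNAs in stem (SD, n = 2), 8070 ± 1937 in SAM (SD, n = 3), 7956 ± 339 in root (SD, n = 2) and 8091 in the endosperm. The embryo listed 3151. At the common read number the stem, SAM, root and endosperm libraries, at 4602 to 5194, all lay above the inflorescence mean of 4493. A number above that of leaf was thus not particular to inflorescence. Among 61936 circRNAs, 60.6% were above 0 in 1 library only and 406 in all 26. ZmCirc007160 was the most abundant in 18 libraries, with a signal of 81187 ± 15252 (SD, n = 6) in inflorescence and 29719 ± 10002 (SD, n = 11) in leaf. The next in summed signal were ZmCirc001962, with 44292 ± 28641 (SD, n = 6) and 16350 ± 7165 (SD, n = 11), and ZmCirc006628, with 44444 ± 17434 (SD, n = 6) and 11256 ± 3471 (SD, n = 11). They were followed by ZmCirc033296, with 55695 ± 22242 (SD, n = 6) and 3764 ± 3882 (SD, n = 11), and ZmCirc039128, with 18281 ± 16048 (SD, n = 6) and 21604 ± 17487 (SD, n = 11).

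**Figure D4:**
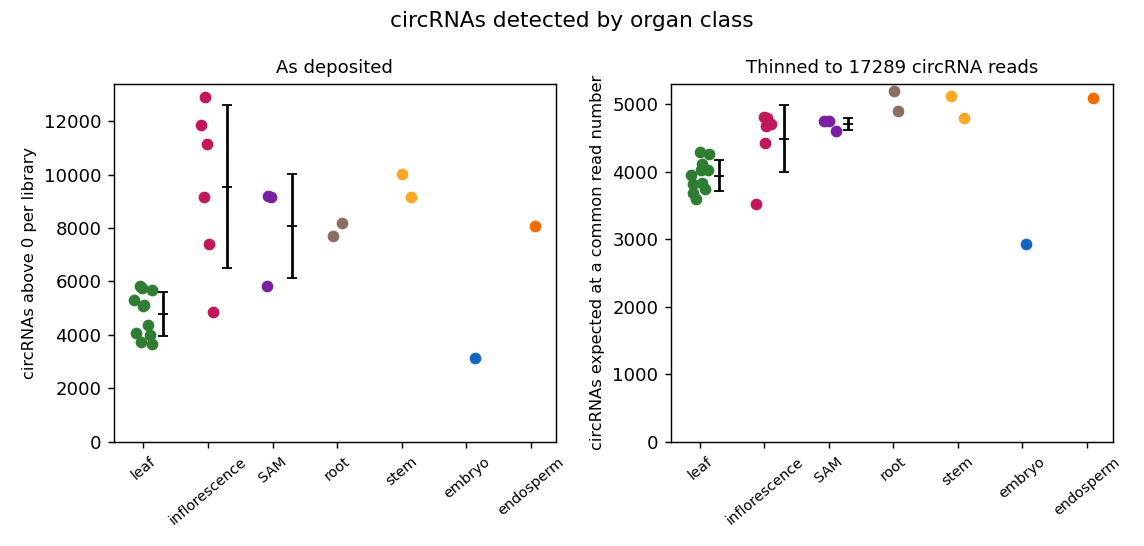
Number of circRNAs above 0 per library (left panel) and expected at 17289 reads per library (right panel) on the vertical axes, by organ class, with 1 point per library and the mean ± SD for classes of 3 or more libraries. As deposited the inflorescence mean is 9551 and the leaf mean 4782, and at the common read number they are 4493 and 3943.

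Of single circRNAs, ZmCirc020983 had a signal of 4438 ± 1585 (SD, n = 6) in inflorescence and was listed at 0 in the 11 leaf libraries. ZmCirc046732 was at 6938 ± 3481 (SD, n = 6) in inflorescence and 117 ± 219 (SD, n = 11) in leaf, a log2 fold change of 6.65 (SE 0.587, adjusted p = 7.14e-12). ZmCirc024928 had a signal of 14805 ± 6016 (SD, n = 11) in leaf and ZmCirc041145 of 4738 ± 3465 (SD, n = 11), and both were listed at 0 in the 6 inflorescence libraries. Of 8989 circRNAs tested with limma, 2683 were higher and 373 lower in inflorescence, with a median shift of 0.63. The test of recovered reads by edgeR gave 3069 higher and 528 lower, and with TMM factors 1975 higher and 774 lower. A pseudocount 10 times larger left 704 calls. Between leaves L and N, limma called 0 of 6655 circRNAs, with 165 at an unadjusted p under 0.05, and edgeR called 4. In simulated data of that size, with the spread fitted to these data, limma recovered 1.52% of changes of 3 on the log2 scale, so it would have missed most differences of that size. The 18.2% recovered by edgeR came from counts with an assumed spread and does not give its power in these data.

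Embryo and endosperm, the parts of the kernel that form the next plant and its store of reserves, had 1 library each and no test. The embryo had 149 entries at least 4-fold above every other library, led by Zm00001d035559 at 416 TPM against at most 0.74 TPM elsewhere and Zm00001d032610 at 197 TPM against at most 0.19 TPM. The endosperm had 506 such entries, with 37.2% of its listed TPM, led by Zm00001d005230 at 1656 TPM against at most 34.2 TPM and Zm00001d027500 at 640.1 TPM against at most 13.6 TPM. For these 4 genes ribosome-bound RNA was also highest in the same tissue, at 1617, 334, 6199 and 992 TPM in the order named.

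The protein list held 365234 pairs among 25147 genes, with a median of 7 partners, and 17.1% of the genes had 1 partner. The most connected protein, Zm00001d032694, had 5024 partners while its gene had a median of 0.355 TPM in total RNA and at most 5.05 TPM, in Primary Root(V1). The next were Zm00001d028918 with 4413, Zm00001d002065 with 3756, Zm00001d045431 with 3064 and Zm00001d027929 with 3050 partners. The 251 genes with most partners took part in 57.4% of pairs. Over 258662 pairs measured in total RNA, the median r of partners across tissues was 0.518, against 0.496 with shuffled partners (range 0.493 to 0.498). The difference was 0.0226, with a permutation p of 0.001, the smallest that 1000 shuffles can give. Within the 11 leaf libraries, an alternative chosen after seeing the data, the difference was 0.00539 (permutation p = 0.005, the smallest that 200 shuffles can give). The list merges pairs from separate cDNA pools, and a pair may need both genes in the same pool. Partners may thus share tissues through the pools, which shuffles over the whole list do not keep. Neither difference can therefore be assigned to the interactions themselves.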

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

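The tests of 1 abundant leaf entry, of 1 ribosome-bound entry, of the library number and of other splits of the libraries were chosen only after the result was seen, except the splits of SAM against inflorescence, while the tests of 100 leaf entries, of the share of listed transcripts and of a few abundant circRNAs were set before their values were known. Among 58 groups of 4 to 10 libraries searched for a library far from the rest, 2 held one, and chance gives about 1 in 20 groups. The 2mm Ear held 0.41 TPM of Zm00001d023516 in total RNA, above 0.01 to 0.09 TPM in the other inflorescence libraries, and the husk leaf held 3.14 TPM of it in ribosome-bound RNA, below 2384 TPM or more in the other leaf libraries.

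More entries were higher in inflorescence than in leaf, with a median log2 difference of 0.65 in total RNA. Without Zm00001d000417, which held 27.3% of the listed TPM in leaf, the median was 0.43 (exact permutation p = 0.00137), which argues against this entry as the whole source. Without the 100 entries of highest TPM in leaf, which held 51.8% of the listed TPM in leaf and 14.7% in inflorescence, it was 0.21 (exact permutation p = 0.0244), less than the bound set for excluding them and more than the bound set for accepting them. This removal takes out entries that are high in leaf and no others, so abundant leaf transcripts and a broader set of transcribed genes in inflorescence cannot be told apart. Both removals also rescaled the other entries to the listed sum, as if it were fixed. The listed entries summed to only 159407 to 395863 TPM per library, a part of the TPM scale. Both falls of the median may therefore overstate this source. Abundant leaf entries may account for part of the shift, of a size that these removals do not give. A difference between organs in the number of transcribed genes stays open. The higher number of entries at 1 TPM or more in inflorescence (17103 against 13296) depends on the same TPM scale.

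The ratio of ribosome-bound to total RNA was mostly higher in inflorescence, in 84.2% of called genes, but in 52.1% after quantile normalization and in 44.9% without Zm00001d019605 and with the other entries rescaled. The 52.1% is partly set by the method, since quantile normalization removes a shared shift, and is not separate evidence on the direction. Zm00001d019605 held under 25% of the ribosome-bound TPM in the husk leaf and at the base of the stage 2 leaf, where the median log2 ratio had a mean of 1.71, against 0.71 ± 0.404 (SD, n = 6) in the other leaf libraries (exact permutation p = 0.0357, the smallest that 28 splits can give) and 1.23 to 1.98 in the 4 inflorescence libraries. The gap of those 2 libraries to inflorescence was thus -26.7% of the gap of the other 6, so this entry may account for the one-sided direction through the fixed TPM sum. The husk leaf and the leaf base also differ from the other leaves in tissue. The husk leaf had the lowest listed total RNA sum, 159407 TPM, and a low sum raises the ratio by itself. The leaf base had a sum of 211393 TPM, above the 203059 TPM of the third leaf. Whether the high share of this gene in leaf ribosome-bound RNA is biological was not tested, since the total RNA table used here does not list it.

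More circRNA reads were found in inflorescence than in leaf. The signal is already divided by the library number, so its ratio of 2.19 does not test depth. Thinned to the smallest library number, the number of detected circRNAs kept a ratio of 1.75 (exact permutation p = 0.000566) of the 2.00 as deposited, which argues against that number as the whole source. Divided by the listed share of total RNA in the same tissue, the ratio was 2.21 (exact permutation p = 0.00299), and without the 5 most abundant circRNAs 2.14 (exact permutation p = 0.000323). Neither step could have removed the ratio, since the mean listed sums were close (259350 TPM in inflorescence, 241139 TPM in leaf) and those 5 circRNAs each held 1.01% to 2.28% of all circRNA reads. Both results therefore add no separate support for the difference. At a common number of circRNA reads the ratio of detected circRNAs was 1.14, a comparison that removes any difference in circRNA yield along with depth. The mean summed signal was 2.96e+06 in inflorescence, 2.38e+06 in stem, 1.92e+06 in SAM, 1.37e+06 in root and 1.35e+06 in leaf, so a signal above leaf was not particular to inflorescence. A higher circRNA content of inflorescence than of leaf may be a biological explanation, while the meaning of the library number and the preparation of the circRNA libraries, which the sources used here do not give, stay open.

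Other splits of the same libraries were counted for each comparison with at least 3 libraries per class, the real split included. At most 100 splits were drawn, of 12376 possible for inflorescence against leaf, 364 for SAM against leaf and 495 for ribosome-bound RNA and its ratio. For total RNA of inflorescence against leaf, 1 of 100 splits gave as many calls (11820, highest other 5462), and for SAM against leaf 1 of 100 (12544, highest other 6697). A random split of these libraries is thus an unlikely source of these counts. The real count was also the largest for ribosome-bound RNA, with 1 of 100 (14886, highest other 11965). The same held for small RNAs of inflorescence against leaf, with 1 of 100 (10278, highest other 7910), and for circRNAs, with 1 of 100 (3056, highest other 2531). In these comparisons the highest other split came nearer to the real count in proportion. For the ratio of ribosome-bound to total RNA 3 of 100 splits gave as many calls, a share under 0.05. Another split gave 5836 calls against 4271, so chance is not excluded there, and a structure among the libraries other than the organ classes may play a part. For SAM against inflorescence 8 of 84 splits gave as many (340, highest other 702), so chance cannot be excluded. For leaves L and N the 8 splits that swap letters within positions are too few for a share under 0.05. There, 1 split gave as many total RNA calls (1087, highest other 0), 3 gave as many small RNA calls (2, highest other 5) and 8 as many circRNA calls (0, highest other 0).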

How the results depend on the processing

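Alternatives added after seeing the data were those without 1 abundant entry, without named pairs of libraries or the 1cm Tassel in inflorescence against leaf, with gene models only, with a mean of 5 TPM, with TMM factors, with thinned reads, all of SAM against inflorescence, and co-expression within the 11 leaf libraries, without the 5 proteins with most partners or in ribosome-bound RNA. The co-expression difference stayed above 0 in every alternative (0.00539 to 0.0242), and the ratio of detected circRNAs stayed above 1 (1.14 to 2.33). Counts of calls moved more, for causes that were not tested. At a pseudocount of 5 the counts were 4785 for inflorescence, 5710 for SAM, 4298 for root and 2732 for stem against leaf, 20 for ear against tassel, 382 for L against N and 146 for SAM against inflorescence. At 0.1 they were 11516 for stem against leaf, 12 for ear against tassel, 2200 for L against N, 1415 for the ratio of ribosome-bound to total RNA, 24800 for small RNAs of inflorescence and 14 for those of L against N. Quantile normalization gave 5923 calls for root. Small RNAs of L against N gave 6 calls with a filter of 10 and 0 with median-ratio rescaling. For circRNAs a pseudocount 10 times larger gave 704 calls in inflorescence, and edgeR gave 4 in L against N, with or without TMM factors. The ratio gave 895 calls among genes with a mean of 5 TPM in both tables, a smaller set, and 7618 without the husk leaf and the base of the stage 2 leaf.

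Without the block that pairs leaf positions, 420 total RNA entries and 0 small RNA features were called between L and N, and the count of circRNAs stayed at 0. Leaving out 1 library, or 1 pair of L and N, gave 10982 to 12795 calls for SAM, 6058 to 7885 for root and 3418 to 6925 for stem against leaf, 24 to 2516 for ear against tassel, 852 to 1181 for L against N, 13981 to 14444 for ribosome-bound RNA, 2667 to 3750 for its ratio, 0 to 9 for small RNAs and 0 for circRNAs of L against N. The lowest values came without Primary Root(6DAS), without Internode(V6), without the 5mm Ear, without the 1cm Tassel for the ratio and without the tip pair for small RNAs. For SAM against inflorescence the range was 156 to 338, with 156 without SAM(V1) and 205 without SAM(V4). Where 1 library of a class was left, it was assumed to vary like the other classes. No library was left out in this way where both classes had more than 5. Of 359 values of named features under alternatives, 347 kept their direction and call, 12 kept their direction and lost the call, and 0 reversed, where the lost calls were of ear against tassel, small RNAs of L against N and SAM against inflorescence. Because the named features were chosen for the largest folds in these data, this was partly set by the choice. Alternatives in which a named feature was no longer tested, as Zm00001d031909 without either root library, are not among the 359. The alternatives on small RNA lengths, on gene lists and on pairs in more than 1 pool were not run. The unknown depth of TPM values and the 17289 reads of the shallowest circRNA library limit what could be detected.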

Other observations

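All descriptions in this part were chosen only after the data were seen, and the splits of SAM against inflorescence are given above. In the endosperm 375 of the 506 entries at least 4-fold above every other library had the ZmLnc prefix and 121 were gene models. In the embryo 138 of 149 such entries were gene models and 7 had the ZmLnc prefix. The husk leaf had 56 such entries with 4.25% of its listed TPM. These counts do not rank tissues, because embryo and endosperm had no other library of their class, while a leaf, ear or SAM entry had to exceed close relatives. Counted by organ, 136 entries were at 10 TPM or more in all 11 leaf libraries and 2-fold above every other library, 224 in both root libraries, 14 in both stem libraries, 1 in the 6 inflorescence libraries and 1 in the 3 SAM libraries. Across tissues, ZmLnc entries had a median specificity index of 0.72, on a scale from 0 for even levels to 1 for a single tissue, against 0.52 for gene models, and 35.0% of them against 12.9% lay above 0.8. The ZmLnc entries also had lower levels, with a median highest value of 5.38 TPM against 10.8 TPM, and low levels can raise this index, so the difference is not separated from level.

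Between SAM and inflorescence limma called 340 entries, 207 higher and 133 lower in SAM, a count for which chance cannot be excluded, since 8 of 84 splits gave as many. It was 156 without SAM(V1) and 205 without SAM(V4), and after quantile normalization 135 were higher and 162 lower. Zm00001d018667 was at 0.04 ± 0.02 TPM (SD, n = 3) in SAM and 44.4 ± 17.6 TPM (SD, n = 6) in inflorescence, a log2 fold change of -5.33 (SE 0.466, adjusted p = 3.34e-07). Zm00001d034045 was at 0.15 ± 0.125 TPM (SD, n = 3) in SAM and 36.0 ± 14.5 TPM (SD, n = 6) in inflorescence, a log2 fold change of -4.90 (SE 0.655, adjusted p = 0.000116). ZmmRNA004993 was at 40.8 ± 39.2 TPM (SD, n = 3) in SAM and 0.715 ± 0.856 TPM (SD, n = 6) in inflorescence, a log2 fold change of 4.26 (SE 0.950, adjusted p = 0.0164). Zm00001d027957 was at 62.8 ± 29.4 TPM (SD, n = 3) in SAM and 4.16 ± 5.48 TPM (SD, n = 6) in inflorescence, a log2 fold change of 4.02 (SE 0.867, adjusted p = 0.0128). Both calls towards SAM were lost in 2 of 7 alternatives, with the direction kept.

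Partners in the protein list were compared with shuffled partners for the direction of their calls. Between inflorescence and leaf, both partners were lower in inflorescence in 1831 pairs against a mean of 1184 with shuffled partners, both higher in 63260 against 61489, and opposite in 15084 against 17101 (permutation p = 0.002 for each, the smallest that 1000 shuffles can give two-sided). Between root and leaf, both partners were lower in root in 412 pairs against 150.8 and opposite in 6077 against 6726. The far more numerous pairs with both higher showed a small excess, 74123 against 73735, just above the shuffled range of 73247 to 74104 (permutation p = 0.002 for each of these directions). Between leaves L and N, both were higher in L in 188 pairs against 142 (permutation p = 0.002), both lower in 135 against 124 (permutation p = 0.3) and opposite in 285 against 280 (permutation p = 0.7).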
